A study of Caenorhabditis elegans with 34 samples.

How the data were processed

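Messenger RNA of C. elegans was measured on 34 spotted arrays that each compared a red and a green channel. On 29 of them RNA of wild-type (N2) or glp-4(bn2) worms was set against a reference pool of wild-type RNA. The worms were at larval stages L2, L3 and L4 or were adults. Titles name the reference in different wordings, a mixed control or REF-vjr, which do not show whether it was the same pool. All adult arrays had the mixed control wording and all L2 arrays REF-vjr, while L3 and L4 arrays of each strain had both. The labels describe glp-4(bn2) worms as lacking a germ line at the restrictive temperature. On the other 5 arrays fem-3(q23) worms, which make sperm and no oocytes, were set directly against fem-1(hc17) worms, which make oocytes and no sperm; the soma is female in both. The labels give growth of the fem worms at the permissive temperature, and when they were shifted to the restrictive one is not given in the sources used here.

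The deposited table holds 1 value per probe and array, taken as a log2 ratio of red over green. Signed values from -8.24 to 10.2 with medians near 0 mark a log ratio. Its base is not given in the sources used here: a base of 10 would need implausibly large ratios, while a natural logarithm was not excluded, so folds hold only if the base is 2. Per the labels, red was the reference pool on the 29 arrays, so their signs were turned to read worm RNA over reference. The fem arrays had fem-3 in red and fem-1 in green on every array, so a dye effect cannot be told from a strain effect. Normalization and spot filtering by the authors are not given in the sources used here. The labels name GenePix scanning for the arrays other than fem-3 against fem-1 replicate 1. That array was scanned with ScanAlyze and reconstructed, and only its normalized ratios are valid per the labels. Values were used as deposited, without further scaling.

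Each of the 13323 probes was fitted with the linear model and empirical Bayes steps of limma (version 3.58.1, R 4.3.3). The 29 reference arrays were fitted together as 8 group means with 1 spread per probe, and the prior degrees of freedom were 2.4. The 5 fem arrays were fitted alone, as a mean against 0. A probe was tested where each group in the comparison had at least 2 values, or at least 3 fem arrays had one. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. Errors beside a log2 change are standard errors of the fit, and those beside group means are standard deviations. The number of arrays limits the precision, and p-values measure the spread between these samples, whose labels number the reference arrays by worm batch; glp-4 L2 replicate 2 pooled a pair of batches. Whether the fem arrays came from separate worm batches is not given in the sources used here. The title of fem replicate 3 repeats that of replicate 2 and marks it as a repeat, so it may not be a separate sample. Spot intensities and background were not given in the sources used here, so no value was filtered on signal.

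Probe names came from the platform annotation: 5582 probes carried a gene name and 7741 did not. By gene ID, 5559 matched the reference gene table (assembly WBcel235), which gave the chromosome. Only 957 probes had a gene-class symbol (letters, hyphen, number), with 949 different symbols. The other named probes, 4625 of them, had a sequence name. As a result, 17 of the 18 gene lists fixed before the data were examined had no member on the arrays and the proteasome list had 1, so none was tested. A further 17 lists were written from the names present, before any set test, although values of some spe genes had been seen. They cover sperm genes, tau-tubulin kinases, small RNA and germ granules, meiosis and chromosome maintenance, oocyte and eggshell, splicing, ribosome biogenesis, transcription, translation, mitochondria, neuropeptides and receptors, pals and irg genes, carboxylesterases, cilia, bus genes, zinc transporters, and GPI anchor and N-glycan synthesis. With 1 probe per gene, each list was tested with limma's cameraPR at a preset correlation of 0.01, and again with camera at an estimated correlation, which took only probes with a value on every array of the fit and so fewer members, with Benjamini-Hochberg adjustment over the lists. The same was done for 32 symbol families of at least 5 genes.

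The comparisons and the rule for naming genes were fixed before the data were examined. For each strain comparison and for fem-3 against fem-1, the rule took the 5 largest changes in each direction among symbol-bearing genes. These had to pass the threshold, with no overlap between the arrays of the groups (or all arrays of 1 sign), and with 1 gene per family. Stage comparisons took 3 in each direction. From each list with a called test or at least 2 called members, the 3 members with the smallest adjusted p were also eligible; applying this part to the later lists was a choice made after the names were seen. A fixed set of marker genes in the rule had no named probe.

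Probes higher in wild type than glp-4 at L4 or in adults were divided by their fem-3 against fem-1 result and tested by Fisher's exact test, as were shares of genes per chromosome. Chromosome tests used 4845 genes that could have entered a class, with adjustment over 24 tests. Probes at least 2-fold different between fem-3 and fem-1 served as a sperm set and an oocyte set, a choice made after the data were seen. The value of a set on an array is its median minus the median of all probes on that array. Neighbouring genes were compared with 10000 shuffles within chromosomes. Neighbours were genes next to each other among the tested genes in reference gene order, so untested genes can lie between them.

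Wild-type and glp-4 arrays shared batch numbers, which did not establish a pair: after removal of group means, correlations between same-numbered arrays ran from -0.047 to 0.217. At L4 all 4 were above 0, from 0.0605 to 0.217. They were not set against differently numbered arrays, so a shared batch component was not excluded. Within glp-4, a number named 1 strain batch across stages, with correlations from -0.0583 to 0.332, and the glp-4 stage comparisons were repeated with the batch as a block. Alternatives were centring each array on its median, quantile normalization, probes with a value on every array, a minimum of 2-fold, fits of the compared arrays alone, blocks for batch number, culture and reference wording, and leaving out each array. Other splits of the arrays were counted for each comparison.

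The fits were tested on simulated data with 200 changed probes per comparison. At 4-fold, 87.5% were recovered in adults, 89.0% at L4, 93.5% at L3, 92.5% at L2 and 95.5% for fem-3 against fem-1. At 2-fold the recovered shares were 46.5%, 62.0%, 45.0%, 26.0% and 46.0% in that order, and at 1.5-fold 0%, 4.5%, 4.0%, 0% and 0%. In the data 4544 probes were called in adults, 2235 at L4 and 4613 for fem-3 against fem-1. With so many changes the adjusted threshold is less strict than with 200, so these shares do not carry over to those comparisons. For fem-3 against fem-1 the false share of calls was 9.80% at 2-fold and 8.61% at 4-fold, above the nominal 5%. It was also above 5% in adults at 4-fold (5.41%) and at L2 at 2-fold (7.14%). At 2-fold it was 5.56% for the L4 against L3 difference and 5.5% for glp-4 L4 against L3. For the adult against L4 difference, 33.3% at 2-fold came from 2 unchanged and 4 changed probes. For glp-4 adult against L4, 50% at 1.5-fold came from 1 of each. Differences between stages were harder to recover: 76.5% at 4-fold and 2.0% at 2-fold for adult against L4, 80.5% and 8.5% for L4 against L3, and 80.0% and 7.0% for L3 against L2. The glp-4 stage comparisons recovered 92.5% and 90.0% at 4-fold, for adult against L4 and L4 against L3. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.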

Results

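RNA levels were measured in wild-type worms and in glp-4(bn2) worms, used per the labels as worms without a germ line, at 4 stages, and between fem-3 mutants, which make sperm, and fem-1 mutants, which make oocytes. The 34 arrays fell into 9 groups. Wild type had 3 arrays at L2, 4 at L3, 4 at L4 and 3 as adults. The glp-4 groups had 3, 4, 4 and 4 arrays in the same order, and fem-3 against fem-1 had 5. Reference arrays held 10155 to 11696 values each, and fem arrays 12215 to 13295. Array medians as deposited ran from -0.088 to 0.324. Labels of 3 arrays disagreed within themselves: wild-type L4 replicate 1 has L3 in its details, wild-type L4 replicate 4 reads L34, and glp-4 L2 replicate 1 has L3 in its source name. The title of glp-4 adult replicate 1 carries the time code T5, where the other adult arrays have T4. The stage in the subcategory of the description was used for each. Every gene given below as a leading change between strains, or between stages of glp-4, had no overlap between the arrays of the groups compared, and those of fem-3 against fem-1 had 1 sign on all arrays.

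The adult comparison asked which RNAs depend on the presence of a germ line. Genes of germ granules and small RNA pathways were among the largest differences. mip-1 (chromosome III), which encodes a LOTUS-domain protein of germ granules, was higher in wild type by 4.23 ± 0.33 log2 (adjusted p = 3.59e-09), with means of 0.89 ± 0.17 (SD, n = 3) in wild type and -3.34 ± 0.50 (SD, n = 4) in glp-4. tost-1 (III), a subunit of a complex that processes small RNA precursors, was higher by 4.21 ± 0.29 (adjusted p = 7.78e-10). gldi-5 (III), msrp-2 (I) and trmt-10A (IV), named as a tRNA methyltransferase, were higher by 4.20 ± 0.42 (2 and 4 arrays), 4.16 ± 0.69 and 4.65 ± 1.53 (2 and 2 arrays). Lower in wild type were cld-1 (IV), by -3.61 ± 0.50 (adjusted p = 3.85e-06), amdh-1 (III) by -2.59 ± 0.42, spi-2 (V) by -2.25 ± 0.63 (3 and 2 arrays), dbd-20 (X) by -2.15 ± 0.71 and spig-12 (IV) by -2.14 ± 0.47. The calls of spi-2 and dbd-20 were lost without wild-type replicate 4, that of dbd-20 also without glp-4 replicate 3, and that of trmt-10A with batch numbers as a block.

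Among the 17 gene lists, written after the gene names had been seen, several of germ cell and growth functions rose in adults with a germ line. Of 14 tested ribosome biogenesis genes all 14 rose, with a median of 1.32 (adjusted p = 3.99e-09). They include the nucleolin gene nucl-1 at 2.65 ± 0.25, the dyskerin gene dkc-1 at 2.78 ± 0.30 and nol-56 at 2.46 ± 0.27. Of 18 meiosis and chromosome maintenance genes 15 rose and 0 fell (median 1.47, adjusted p = 1.21e-08). The SMC5/6 subunit gene nse-4 stood at 3.05 ± 0.26, the synaptonemal complex gene syp-6 at 2.68 ± 0.24 and the DNA polymerase gene pold-1 at 2.67 ± 0.30. In the splicing list 23 of 28 rose and 0 fell (median 1.12, adjusted p = 7.05e-11), led by sluh-7 at 2.98 ± 0.29, syf-1 at 1.73 ± 0.19 and cwf-19L1 at 1.57 ± 0.19. Small RNA and germ granule genes rose in 9 of 12 cases (adjusted p = 1.75e-05), among them lotr-1 at 2.87 ± 0.28. Transcription genes rose in 9 of 11 (median 1.13, adjusted p = 9.16e-05), including rpap-2 at 1.78 ± 0.23, gtf-2H3 at 1.71 ± 0.23 and the Integrator gene ints-7 at 2.05 ± 0.28. The adjusted p with an estimated correlation was 0.0449 for transcription and 0.0401 for the other 4 lists of this paragraph. That test took only members with a value on every array: 6 for ribosome biogenesis, 10 for meiosis, 23 for splicing, 10 for small RNA and 8 for transcription.

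Translation genes rose in 6 of 8 cases (median 1.06, adjusted p = 0.00212), with eif-2A at 2.16 ± 0.23; adjusted p = 0.135 with an estimated correlation. GPI anchor and N-glycan genes rose in 6 of 10 (adjusted p = 0.00460, and adjusted p = 0.121 with an estimated correlation), with pgap-1 at 2.01 ± 0.23 and algn-6 at 1.35 ± 0.18. Sperm genes had 2 of 7 higher (median 0.54, adjusted p = 0.0440, and adjusted p = 0.162 with an estimated correlation), the spermatogenesis gene spe-18 at 2.59 ± 0.34 and the paternal granule gene pei-1 at 1.02 ± 0.25. Carboxylesterases, mainly intestinal enzymes, had 11 of 27 lower and 1 higher (median -0.65, adjusted p = 0.00111, and adjusted p = 0.140 with an estimated correlation). Among these cest-35.1 fell by 1.44, cest-17 fell by 1.40 and cest-8 fell by 1.36. The pals and irg genes had 9 of 23 lower (median -0.52, adjusted p = 0.00352, and adjusted p = 0.0401 with an estimated correlation on 14 members), with pals-32 at -1.07 ± 0.28 and pals-23 at -0.91 ± 0.18. Neuropeptide and receptor genes had 4 of 20 lower (median -0.51, adjusted p = 0.0420, and adjusted p = 0.140 with an estimated correlation), with nlp-101 at -1.13 ± 0.26 and nlp-55 at -1.09 ± 0.23.

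The test was not passed in adults by mitochondrial genes (3 of 19 higher, 1 lower), tau-tubulin kinases (3 of 6 higher, 1 lower) or oocyte and eggshell genes (2 of 5 higher). Nor was it passed by zinc transporters (3 of 6 higher, 2 lower), bus genes (2 of 6 lower) or cilia genes (0 of 8 either way). Members nevertheless changed: memi-3 and oops-1, both oocyte genes, rose by 2.89 ± 0.36 and 2.59 ± 0.40, the zinc transporters zipt-11 and zipt-1 rose by 1.87 ± 0.29 and 1.52 ± 0.24, while zipt-2.1 fell by 1.64 and bus-6 fell by 1.60. The median of the oocyte and eggshell list was 0.01 and turned to -0.04 with centred arrays. Its members did not move together: cpg-22 stood at -0.89 ± 0.37, not called, while memi-3 and oops-1 rose. Over all 11402 probes tested with limma, 2313 were higher and 2231 lower in wild-type adults. Of these, 1676 and 1040 differed at least 2-fold. With only the adult arrays fitted, 1802 were higher and 1249 lower. The median of all probes was -0.17, and list medians are read against it.

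At L4 the named genes with the largest wild-type excess were also higher in the sperm-making fem-3 worms. msrp-2 was higher in wild type by 5.56 ± 0.69 (3 and 4 arrays, adjusted p = 2.55e-06), cylc-2 (I) by 4.19 ± 0.37 (adjusted p = 2.43e-08), melo-3 (V) by 3.73 ± 0.39, spsp-1 (I) by 3.41 ± 0.28 and the claudin-like gene clc-10 (III) by 3.33 ± 0.48. cylc-2 had means of 2.60 ± 0.88 (SD, n = 4) in wild type and -1.58 ± 0.32 (SD, n = 4) in glp-4. Lower in wild type were cld-1 by -2.73 ± 0.46, mbug-1 (IV) by -1.69 ± 0.38 and erp-44.2 (IV), named for a thioredoxin-like protein of the endoplasmic reticulum, by -1.60 ± 0.41. The carboxylesterase gene cest-35.1 (V) and the cathepsin B-like gene cpr-9 (V) were lower by -1.23 ± 0.19 and -1.14 ± 0.34. The calls of mbug-1, erp-44.2 and cpr-9 were lost within each reference wording, and that of cpr-9 also without wild-type replicate 1 or 3 or glp-4 replicate 1.

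Sperm genes rose at L4 in 3 of 7 cases (median 0.57, adjusted p = 0.00492), spe-18 by 3.04 ± 0.32 and pei-1 by 1.60 ± 0.25. Tau-tubulin kinases rose in 3 of 5 (median 0.65, adjusted p = 0.00329), ttbk-4 by 2.57 ± 0.28 and ttbk-8.1 by 2.42 ± 0.29. Small RNA and germ granule genes rose in 6 of 12 (median 0.95), with mip-1 at 3.08 ± 0.31, and meiosis genes in 7 of 19 (median 0.73), with syp-6 at 1.79 ± 0.22. Ribosome biogenesis genes rose in 5 of 14 (median 0.49), with nucl-1 at 1.85 ± 0.23, splicing genes in 8 of 27 (median 0.39) and transcription genes in 3 of 12 (median 0.46). Carboxylesterases fell in 11 of 27 (median -0.61, adjusted p = 4.21e-05) and pals and irg genes in 4 of 23 (median -0.42, adjusted p = 0.0228). No call of these lists held with an estimated correlation: the adjusted p with an estimated correlation was 0.181 for splicing, 0.192 for transcription and 0.143 for the others, and the kinase list had too few complete probes for it. limma placed 1329 probes higher and 906 lower at L4, of 11220 tested. Arrays of the 2 reference wordings gave 1052 and 742 probes when each was fitted alone, with fewer arrays, and 2292 with the wording as a block.

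At L3, mip-1 was higher in wild type by 2.23 ± 0.31 (adjusted p = 1.42e-04), egc-2 (IV) by 2.2 ± 0.38, nucl-1 by 1.58 ± 0.25 (4 and 3 arrays), the F-box gene fbxl-2 (III) by 1.32 ± 0.25 and gex-5 (III) by 1.28 ± 0.35. cld-1 was lower by -2.42 ± 0.46 (adjusted p = 0.00366). The carboxylesterase gene cest-32 (V), the F-box gene fbxc-58 (IV), nspg-11 (IV) and the nicotinamide riboside kinase gene nmrk-1 (I) were lower by -0.93 ± 0.25, -0.91 ± 0.15, -0.75 ± 0.19 and -0.73 ± 0.20. Meiosis genes rose in 3 of 17 cases (median 0.44, adjusted p = 2.97e-04), led by the cohesion gene ctf-18 at 0.89 ± 0.17 and syp-6 at 1.05 ± 0.22. The small RNA list had 2 of 11 higher (median 0.60, adjusted p = 0.0248), ribosome biogenesis 1 of 14 (median 0.36) and splicing 1 of 28 (median 0.18). Carboxylesterases had 2 of 26 lower (median -0.29) and pals and irg genes 1 of 22 (median -0.19). With an estimated correlation none of these lists passed, with an adjusted p of 0.240 for meiosis and carboxylesterases, 0.266 for small RNA, 0.205 for ribosome biogenesis and for pals and irg, and 0.347 for splicing. In all, 239 probes were higher and 120 lower of 11112 tested with limma. The count fell to 29 when the 8 arrays of this stage were fitted alone and to 46 and 16 within each reference wording; it was 394 with the wording as a block, and gex-5, nmrk-1, nspg-11 and cest-32 lost their calls both alone and within each wording. Without wild-type replicate 1 or 2 it was 178 or 188, and without glp-4 replicate 1 or 2 it was 194 or 148.

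At L2 few genes differed. lhpp-1 (V), named for a phosphatase, was the named gene that met the rule, lower in wild type by -2.37 ± 0.46 (2 and 3 arrays, adjusted p = 0.0275). Its means were -1.02 ± 1.30 (SD, n = 2) in wild type and 1.35 ± 1.05 (SD, n = 3) in glp-4. The error of the change rests on the spread shared by all groups and does not show this scatter. Genes of mitochondrial respiration and import lay higher as a list (18 tested, median 0.60, adjusted p = 2.84e-09), although 0 single members passed; adjusted p = 0.147 with an estimated correlation. The pyruvate carrier gene mpc-1 stood at 1.21 ± 0.29 and the complex I gene ndub-6 at 1.02 ± 0.25, each with an adjusted p of 0.0601. Ribosome biogenesis (median 0.43), translation (0.34), splicing (0.32) and meiosis (0.26) lists were also called higher, at adjusted p = 0.00131, 0.0147, 0.0195 and 0.0195, with 0 members past the threshold. For them the adjusted p with an estimated correlation was 0.355, 0.319, 0.355 and 0.423. limma gave 23 probes higher and 20 lower of 10272. The count rested on single arrays: it was 299 without glp-4 replicate 1, whose source name reads L3 and which correlated better with wild-type L2 arrays (0.766) than with its own group (0.651), and 10, 11, 13, 14 and 16 without glp-4 replicate 2, glp-4 replicate 3 and wild-type replicates 1, 2 and 3. It was 0 when the 6 arrays were fitted alone, where 43 had been called in the shared fit.

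**Figure D1:**
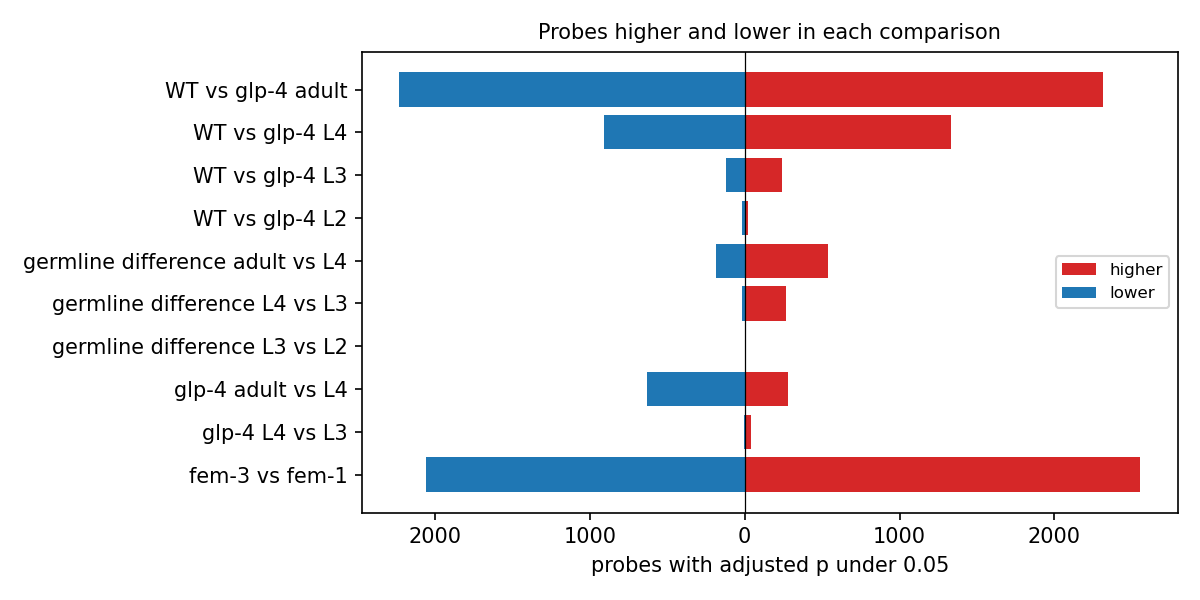
Number of probes with an adjusted p under 0.05 in each comparison (horizontal axis), with higher probes to the right of 0 and lower probes to the left. In the strain comparisons the counts of higher probes were 23 at L2, 239 at L3, 1329 at L4 and 2313 in adults.

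**Figure D2:**
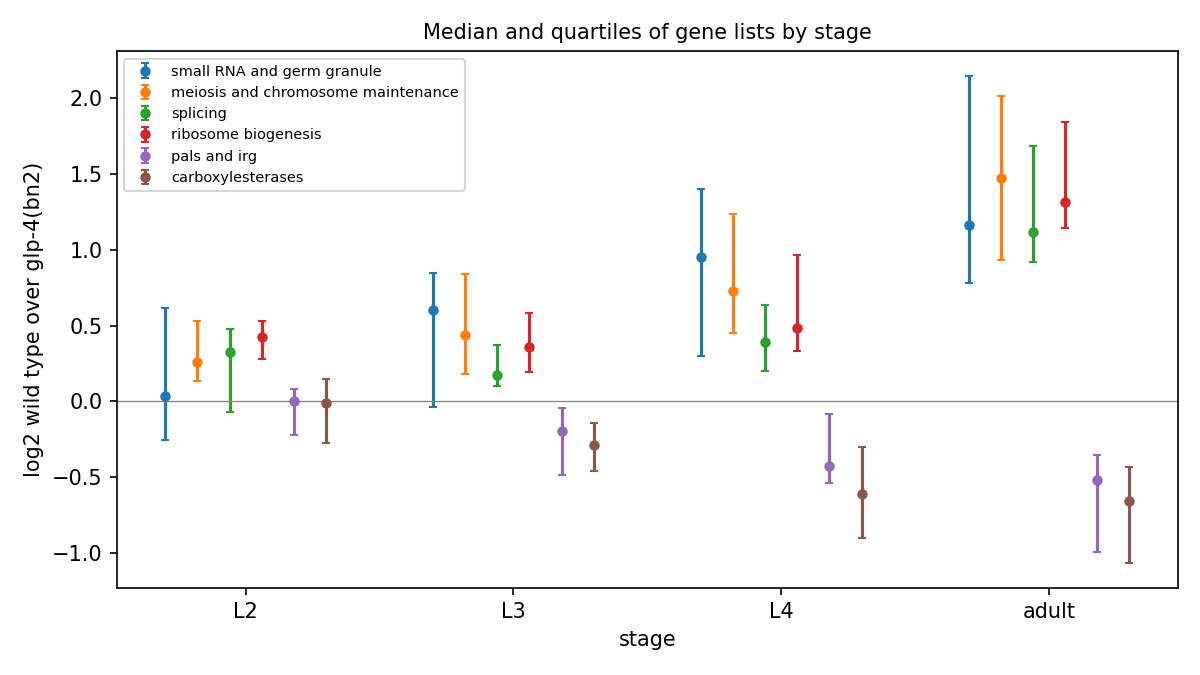
Log2 ratio of wild type over glp-4(bn2) (vertical axis) for 6 gene lists at each stage, with points for the median of the members and bars for their quartiles. The ribosome biogenesis median was 0.43 at L2 and 1.32 in adults, and that of the carboxylesterases was -0.65 in adults.

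Tests of the strain difference itself between stages asked for which genes this difference changed. A gain can come from a rise in wild type or from a fall in glp-4, which these tests do not separate. From L4 to adult the wild-type excess grew by 2.35 ± 0.39 for tost-1, by 2.12 ± 0.36 for fbxl-2 and by 2.08 ± 0.40 for sluh-7. The change was -2.29 ± 0.58 for amdh-1, -1.65 ± 0.41 for spsp-1 and -1.64 ± 0.47 for the NYN-domain gene nyn-3 (II). In glp-4 alone sluh-7 changed by -1.04 ± 0.27 from L4 to adult (limma adjusted p = 0.0169), so part of its gain was a fall in glp-4. For tost-1 the change in glp-4 was -0.32 ± 0.27, not called. Ribosome biogenesis genes also lay lower as a list in glp-4 adults, a call lost with an estimated correlation. Splicing genes gained in 9 of 27 cases (median 0.78, adjusted p = 1.35e-10) and meiosis genes in 5 of 17 (median 0.89, adjusted p = 4.26e-07), including ctf-18 at 1.46 ± 0.28. Ribosome biogenesis gained in 2 of 14 (median 0.80), transcription in 4 of 11 (0.94), small RNA in 3 of 12 (0.55), GPI anchor and N-glycan in 2 of 10 (0.71) and translation in 1 of 8 (0.81). The adjusted p with an estimated correlation was 0.120 for translation and 0.0805 for the other 6 lists. limma placed 539 probes higher and 188 lower of 11043. This count was 253 when only the 15 arrays compared were fitted, where amdh-1, spsp-1 and nyn-3 lost their calls. It was 1121 without wild-type L4 replicate 2, which lay near the adults, 1096, 366 and 260 without wild-type adult replicates 3, 2 and 4, 398 and 342 without wild-type L4 replicates 1 and 3, and 474, 368 and 419 without glp-4 L4 replicates 2, 3 and 4.

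From L3 to L4 the wild-type excess grew by 3.48 ± 0.93 for msrp-2, 3.22 ± 0.53 for cylc-2 and 2.83 ± 0.40 for spsp-1, all of which were also higher in wild type at L4. pugs-2 (II) and the Golgi pH regulator gene gphr-2 (X) changed by -1.67 ± 0.44 and -0.69 ± 0.18. Of these 5 genes, msrp-2, pugs-2 and gphr-2 lost the call when only the arrays compared were fitted, and each lost it without most of the single arrays left out in turn. Tau-tubulin kinases gained in 2 of 5 cases (median 0.47, adjusted p = 0.00250), ttbk-8.1 by 2.24 ± 0.42 and ttbk-4 by 1.98 ± 0.39. The small RNA list was called higher (median 0.52, adjusted p = 0.00250) and the carboxylesterases lower (median -0.28, adjusted p = 0.0465), both with 0 members past the threshold and with an adjusted p of 0.455 and 0.501 with an estimated correlation. In this comparison 270 probes were higher and 18 lower of 10936, by limma. The count was 186 with the arrays compared alone and 485 (384 higher, 101 lower) without wild-type L4 replicate 4, the array labelled L34; other splits of the arrays gave as many in 5 of 100 cases, the real one included.

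Between L2 and L3 no probe of 10181 passed the limma threshold for a changed strain difference, against 795 with an unadjusted p under 0.05. The mitochondrial list shifted, with a median of -0.67 over 18 genes (adjusted p = 2.14e-08, and adjusted p = 0.217 with an estimated correlation), and carboxylesterases by -0.30 (adjusted p = 0.01, and adjusted p = 0.511 with an estimated correlation). The count was 33 without glp-4 L2 replicate 1, 30 without wild-type L3 replicate 4, 3 without glp-4 L3 replicate 1, and 2 and 1 without wild-type L3 replicates 2 and 1.

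The glp-4 worms also changed between stages. From L4 to adult in glp-4, stha-3 (X) rose by 4.39 ± 0.52 (adjusted p = 3.32e-05). The uterine lumen gene ule-3 (V) rose by 3.05 ± 0.43 and the trypsin-like protease gene try-14 (X) by 2.86 ± 0.50. rml-3 (X), spia-1 (X) and gtnt-16 (V) fell, with changes of -3.26 ± 0.60, -3.23 ± 0.61 and -3.06 ± 0.54. Carboxylesterases fell in 3 of 27 cases (median -0.41) and ribosome biogenesis genes in 3 of 14 (median -0.36), both at adjusted p = 0.0195, with an adjusted p of 0.542 and 0.652 with an estimated correlation. limma placed 282 probes higher and 629 lower in adults, of 11326. With the strain batch as a block the count was 451, and with centred arrays the division was 410 higher and 433 lower. The adult arrays all had the mixed control wording of the reference, while the L4 arrays had both wordings. With the wording as a block 936 were called, of which 751 were among the 911 of the main fit. Fitting the 8 arrays alone gave 488, quantile normalization 573, and leaving out glp-4 L4 replicate 4 or 3 gave 548 or 561, while without glp-4 adult replicate 1, titled T5, 186 were higher and 442 lower.

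From L3 to L4 in glp-4, the chondroitin proteoglycan gene cpg-22 (I) rose by 1.60 ± 0.34 (adjusted p = 0.0294), a call that was lost with the strain batch as a block. Its list, named oocyte and eggshell, was called higher with 1 of 5 past the threshold (median 0.09, adjusted p = 0.0239, and adjusted p = 0.0562 with an estimated correlation). The member past it, cpg-22, was not called higher in wild-type adults (-0.89 ± 0.37) or in fem-1 (-0.11 ± 0.17). The list name therefore does not show a rise of oocyte RNA in glp-4. Ribosome biogenesis genes were lower as a list (14 tested, median -0.43, adjusted p = 3.03e-08, and adjusted p = 0.0562 with an estimated correlation), as were splicing genes (27 tested, median -0.23, adjusted p = 6.63e-04, and adjusted p = 0.377 with an estimated correlation), with 0 members of either past the threshold. Carboxylesterases lay higher (26 tested, median 0.20, adjusted p = 0.00106, and adjusted p = 0.225 with an estimated correlation). By limma 38 probes were higher and 3 lower of 11181, and 27 were called with the batch as a block. The count was 20 with the 8 arrays fitted alone and 20, 25 and 24 without glp-4 L3 replicate 4 and glp-4 L4 replicates 2 and 1.

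The direct comparison of fem-3 with fem-1 worms separated RNAs of sperm-making and oocyte-making animals. clc-10 was higher in fem-3 by 6.09 ± 0.21 (adjusted p = 4.65e-06, n = 5), melo-3 by 6.06 ± 0.18 (n = 5) and cylc-2 by 5.61 ± 0.25 (n = 5). spe-18, needed in spermatogenesis, was higher by 5.37 ± 0.18 (n = 5) and the kinase gene ttbk-4 (IV) by 5.36 ± 0.20 (n = 3) on 1 probe and 3.98 ± 0.18 on the other. Higher in fem-1 were gldi-5 at -2.19 ± 0.22, srdf-2.1 (X) at -2.07 ± 0.20, the nuclear RNA interference gene enri-2 (X) at -2.02 ± 0.21, atz-1 (IV) at -1.94 ± 0.18 and the replication fork gene ctf-4 (V) at -1.94 ± 0.17. mip-1, higher in wild-type adults, stood at -1.54 ± 0.17.

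Sperm genes were higher in fem-3 in 8 of 9 cases (median 2.27, adjusted p = 4.37e-05), including spe-58 at 5.01 ± 0.25 and spe-57 at 2.27 ± 0.19. Tau-tubulin kinases were higher in 5 of 7 (median 1.79, adjusted p = 5.37e-04), with ttbk-8.1 at 4.58 ± 0.19. Higher in fem-1 were 19 of 32 splicing genes (median -0.79, adjusted p = 7.46e-08), such as cwf-19L2 at -1.34 ± 0.15, and 11 of 15 ribosome biogenesis genes (median -0.86, adjusted p = 3.03e-06), such as ddx-52 at -1.21 ± 0.16 and dkc-1 at -1.13 ± 0.15. The same direction was taken by 10 of 22 meiosis genes (median -0.48, adjusted p = 1.37e-05), with szy-5 at -1.56 ± 0.18, and by 7 of 14 small RNA genes (median -0.51, adjusted p = 0.00125), with tost-1 at -1.54 ± 0.18. Transcription (5 of 13, median -0.39), translation (5 of 9, median -0.48), GPI anchor and N-glycan (5 of 13, median -0.28) and mitochondrial genes (7 of 23, median -0.20) were also called higher in fem-1. No list call held with an estimated correlation: the adjusted p with an estimated correlation was 0.161 for the kinases, 0.132 for translation, 0.254 for mitochondrial genes and 0.113 for the others.

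Neuropeptide and receptor genes were higher in fem-3 in 7 of 23 cases (4 with centred arrays; list test adjusted p = 0.0792), with nlp-51 at 1.45 ± 0.14. The lists of oocyte and eggshell genes (2 of 5 higher in fem-1, adjusted p = 0.0509), pals and irg genes (2 of 24 higher in fem-3), carboxylesterases (3 of 29 higher in fem-3), cilia (1 of 10 higher in fem-1), bus genes (1 of 6 higher in fem-3) and zinc transporters (2 of 8 higher in fem-1) did not pass. memi-3 and oops-1 were higher in fem-1, at -1.57 ± 0.18 and -1.07 ± 0.15, and zipt-1 stood at -1.38 ± 0.14. The median of the zinc transporters was 0.13 and turned to -0.04 with centred arrays, while their list test pointed to fem-1. Of 13284 probes, limma placed 2555 higher in fem-3 and 2058 higher in fem-1, and 1350 and 873 of these differed at least 2-fold. The median of all probes was 0.16, and centring the arrays turned the division to 1913 and 2445. Without replicate 4 the count was 2930 and without replicate 5 it was 2903.

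Probes higher in wild type than in glp-4, here called germline probes, were then divided by their fem-3 against fem-1 result. Both comparisons used whole worms, so the origin of these RNAs in germ cells was not tested. Of 2567 probes higher in wild type at L4 or in adults, 1211 (47.2%) were higher in fem-1, against 419 expected (odds ratio 11, 95% interval 9.81 to 12), and 618 (24.1%) were higher in fem-3, against 484 expected (odds ratio 1.51, 1.35 to 1.68, Fisher's exact p = 7.29e-14). The other 738 passed in neither direction, which does not show that they were equal. Of the 255 probes higher at L4 and not called in adults, 198 were higher in fem-3 (odds ratio 16.3, 95% interval 12.1 to 22.4) and 7 in fem-1. Of the 1238 called in adults and not at L4, 39 were higher in fem-3 (odds ratio 0.124, 0.0876 to 0.172) and 724 in fem-1. With germline defined in adults alone, the share higher in fem-3 did not exceed chance (420 of 2312, odds ratio 0.944, Fisher's exact p = 0.342). Among the 2426 probes lower in wild type, 502 were higher in fem-3 and 92 in fem-1. Of 1326 probes higher at L4 and tested in both stages, 1074 were also higher in adults (277 expected), and of 239 higher at L3, 201 were also higher at L4 (29 expected).

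Probe sets taken from the fem arrays, a choice made after the data were seen, were followed across the stages. The 1350 sperm-set probes had a median wild type over glp-4 ratio of -0.07 at L2, 0.14 at L3, 0.77 at L4 and 0.33 in adults, with 558 of 1122 higher and 33 lower at L4, and 392 of 1135 higher and 113 lower in adults. As a set they were higher at L4 (camera p = 6.12e-04 with an estimated correlation) but not past the threshold in adults (p = 0.182 with an estimated correlation). The median changed by 0.67 from L3 to L4 (camera p = 3.88e-05 with an estimated correlation) and by -0.46 from L4 to adult (p = 0.0276 with an estimated correlation). The 873 oocyte-set probes had medians of 0.18 at L2, 0.24 at L3, 0.46 at L4 and 1.51 in adults, with 258 of 776 higher and 9 lower at L4, and 573 of 790 higher and 15 lower in adults (set p = 0.0514 and 0.00123 with an estimated correlation). Their change from L4 to adult was 1.02 (p = 9.33e-04 with an estimated correlation). On single arrays, set values were taken relative to the median of all probes. The sperm set averaged 0.83 ± 0.17 (SD, n = 4) in wild-type L4 worms and 0.38 ± 0.09 (SD, n = 3) in adults. The oocyte set averaged -0.44 ± 0.31 (SD, n = 4) and 0.57 ± 0.20 (SD, n = 3). Wild-type L4 replicate 2 stood apart in the oocyte set, at 0.0045 against -0.66 to -0.45 on the other L4 arrays.

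**Figure D3:**
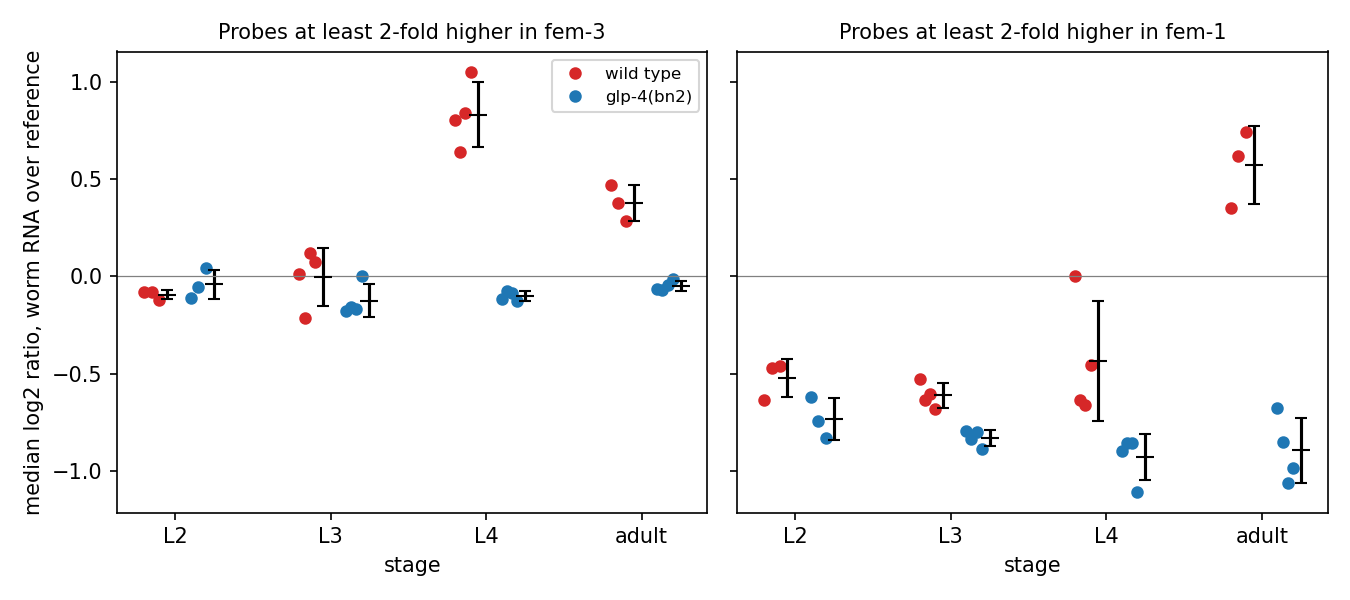
Median log2 ratio of worm RNA over reference on each array, minus the median of all probes on that array (vertical axis). Panels hold probes at least 2-fold higher in fem-3 (left) and in fem-1 (right), by stage and strain. The mean and SD stand beside the points. The sperm set averaged 0.83 in wild-type L4 worms, and the oocyte set averaged 0.57 in wild-type adults.

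Germline genes were unevenly spread over the chromosomes. Of 443 germline genes higher in fem-3, 2 (0.452%, exact 95% interval 0.0547 to 1.62) lay on chromosome X, which holds 16% of the 4845 tested genes (odds ratio 0.0207, Fisher's exact test, adjusted p = 1.20e-31). These 2 genes, named after their values were seen, were D1053.5, at 4.28 ± 0.17 in fem-3 against fem-1, and F17H10.4, at 0.63 ± 0.16. Of germline genes higher in fem-1, 24 of 472 (5.08%, interval 3.29 to 7.47) were X-linked (odds ratio 0.251; with a minimum of 2-fold 18 of 205, 8.78%, odds ratio 0.480), and of those in neither class 15 of 286 (5.24%, odds ratio 0.269). Genes lower in wild type than glp-4 were X-linked in 227 of 1015 cases (22.4%, odds ratio 1.66, adjusted p = 7.14e-08). Genes higher in fem-3 were more frequent on chromosomes I (22.8%, odds ratio 1.90) and IV (26.9%, odds ratio 2.12), and those higher in fem-1 on I (21.6%, odds ratio 1.76) and III (odds ratio 2.11). Chromosome V held fewer of both than of all genes, with odds ratios of 0.580 and 0.593. Genes are not independent replicates, since neighbours can be expressed together.

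**Figure D4:**
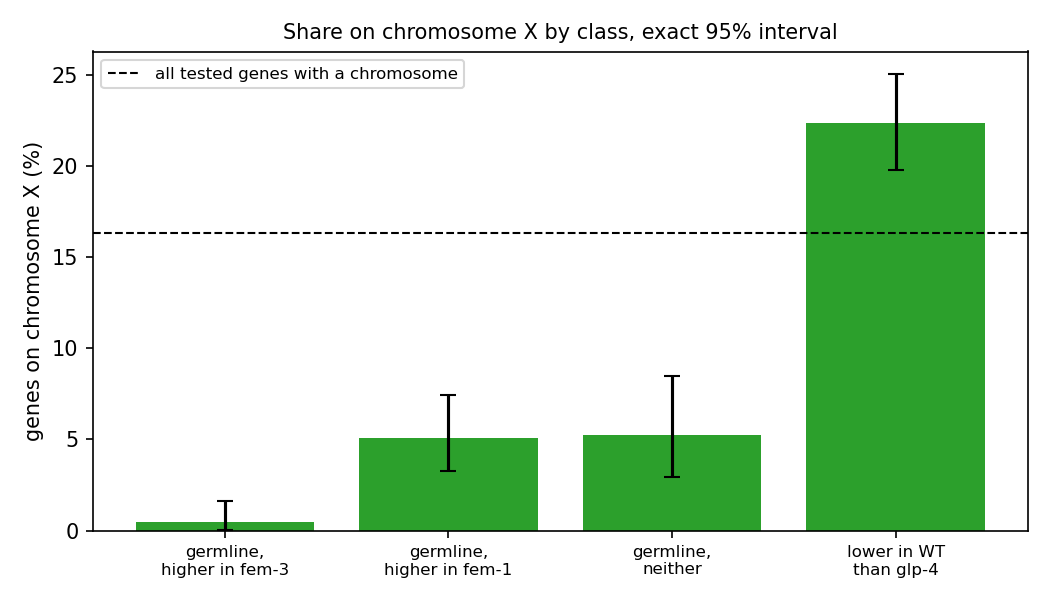
Share of genes on chromosome X (vertical axis, percent) in each class, with exact 95% intervals as bars and the share among all tested genes as a dashed line at 16%. Germline genes higher in fem-3 lay at 0.452%, and genes lower in wild type than in glp-4 at 22.4%.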

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

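Of the tests in this part, those on wild-type L4 replicate 2, those of 4 or 5 lists or with cilia genes, and the sorting of splits by exchanged strains were chosen only after the result was seen, and the tests on chromosome X and on carboxylesterases against neuropeptides were not planned at the outset but written before their own results.

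Among 87 groups of 4 or 5 arrays tested for a far array, 6 held one, where chance gives about 5% of groups. clc-10 stood at -0.68 in glp-4 L4 replicate 4, against -1.26 to -1.18 on the other arrays of its group. mip-1 stood at -2.52 in glp-4 L3 replicate 3, against -3.60 to -3.51. sluh-7 stood at -2.24 in glp-4 adult replicate 3, against -1.71 to -1.60. gtnt-16 stood at 1.07 in glp-4 L4 replicate 4, against 0.36 to 0.37. The sperm set stood at 0.00 in glp-4 L3 replicate 1, against -0.18 to -0.15. The oocyte set stood at -1.11 in glp-4 L4 replicate 1, against -0.90 to -0.85.

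The strain difference itself differed between L4 and adult for 727 probes. Among named genes the difference of differences was 2.35 for tost-1, 2.12 for fbxl-2, 2.08 for sluh-7, -2.29 for amdh-1, -1.65 for spsp-1 and -1.64 for nyn-3. Between L3 and L4 it differed for 288 probes, by 3.48 for msrp-2, 3.22 for cylc-2, 2.83 for spsp-1, -1.67 for pugs-2 and -0.69 for gphr-2.

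Other splits of the same arrays into groups of the same sizes were counted, the real one included. The real split gave the most probes for the strain comparison in adults (1 of 35 splits, 4544 probes, highest other 2805). The same held at L4 (1 of 35, 2235, highest other 205) and at L3 (1 of 35, 359, highest other 53). A share of 1 of 35 is the smallest these splits can give and was not adjusted over the comparisons, so chance was not excluded. The real split also gave the most for the glp-4 steps from L4 to adult (1 of 35, 911, highest other 2) and from L3 to L4 (1 of 35, 41, highest other 3). These splits ignored the strain batches shared across glp-4 stages. With the batch as a block the counts were 451 and 27. The splits were too few for a share under 0.05 at L2 (1 of 10, 43 probes, highest other 13) and for fem-3 against fem-1 (1 of 16, 4613 probes, highest other 21). For the change from L4 to adult, 4 of 100 splits gave as many as 727 probes, with 3093 as the highest other. This share lies just under 0.05 and was not adjusted over the comparisons, so chance was not excluded. For the change from L3 to L4, 5 of 100 gave as many as 288, with 1950 as the highest other, so this count did not exclude chance. The sperm set taken from the fem arrays, a test of the set and not of the count, changed at that step by 0.67 (camera p = 3.88e-05 with an estimated correlation). For L2 to L3 the real count was 0, which any split must reach, so the 100 splits say nothing on chance there. The highest other was 101. The splits that called several times the real count point to a structure of the samples: exchanging the strains in 1 stage turns a difference of strain effects into their sum. All 3 of the other large splits from L4 to adult, and 3 of the 4 from L3 to L4, mostly exchanged the strains in 1 stage alone. The highest of the remaining splits were 184 and 819 probes, so from L3 to L4 1 split of another kind also exceeded the real count.

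Wild-type L4 replicate 2 lay near the adult arrays. Its oocyte set stood at 0.0045, against -0.66 to -0.45 on the other L4 arrays and at least 0.351 on adult arrays, and its mean correlation across probes with the adult arrays was 0.619, against at most 0.457 for the other L4 arrays. A swap with wild-type adult replicate 2 is argued against, since that array correlated less with the other L4 arrays than with the other adult arrays, by -0.292. An adult array wrongly labelled L4 is argued against by its sperm set, which stood at 0.80, above the highest adult array (0.472) by 1.75 times the range of the adult arrays. Older worms in this batch and a mixture with adult RNA cannot be told apart, since the gap of its oocyte set to the other L4 arrays, 2.22 times their range, only restates the position, and without this array the L4 count was 1571 and the adult against L4 count 1121.

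Probes lower in wild-type than in glp-4 adults numbered 2231, and 1249 with only the adult arrays fitted. With centred arrays 2505 were called lower. Centring the deposited ratios cannot undo an earlier normalization by the authors, so normalization as the source was not tested. Dilution of all somatic RNA by germline RNA could lower every somatic gene alike: the medians of the carboxylesterases (27 genes, mainly intestinal) and the neuropeptide and receptor genes (20 genes, neuronal) differed by -0.14, with a bootstrap interval from -0.44 to 0.23 and a two-sided permutation p of 0.322. Over 84 genes of 5 lists taken as somatic, with pals and irg, cilia and bus genes added, the permutation p was 0.0721, and with the range of medians over the 4 lists without bus genes it was 0.0385. The 8 cilia genes went against an equal fall, since the carboxylesterases lay below them by -0.58 (interval -0.89 to -0.20, permutation p = 0.0107), the smallest of 3 such comparisons (0.0411 for neuropeptides, 0.0405 for pals and irg). Equal dilution and a change of somatic expression cannot be told apart here, because the tests over all lists disagree and germline expression of the listed genes was not tested.

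Germline genes higher in fem-3 were rare on chromosome X. Runs of neighbouring genes counted many times over are argued against, since with 1 gene per run the upper 95% bound of the odds ratio was 0.0988. Gaps in the values of tested X-linked genes are argued against by an upper bound of 0.118 among genes with a value on every array. X-linked genes with too few values to be tested are absent with and without this restriction. It therefore cannot show whether such genes were lost, and weak spots were not tested. No biological explanation was tested, and germline genes higher in fem-1 or in neither class were also rare on chromosome X, with odds ratios of 0.251 and 0.269. Probes without a gene name could not be placed, which leaves their share on chromosome X open.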

How the results depend on the processing

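The tests of chromosome X shares with 1 gene per run or with complete values, of germline classes with centred arrays, and of the 17 gene lists were chosen after the data were seen; the others were planned. The count for the adult strain comparison stayed within 1.5 times of 4544 under each alternative except the 2-fold minimum, but with only the adult arrays fitted its division moved from 2313 higher and 2231 lower to 1802 and 1249. Germline probes higher in fem-3 ranged from 420 to 625 of a reported 618 under the alternatives, and their share on chromosome X from 0.292% to 0.702%. The share of those higher in fem-1 ranged from 4.76% to 8.78% around 5.08%, and their odds ratio was 0.480 (0.277 to 0.786) with a minimum of 2-fold. Each list call held with centred arrays, where members past the threshold fell from 7 to 4 for neuropeptides and 2 to 1 for pals and irg in fem-3 against fem-1, from 4 to 2 for transcription and 2 to 1 for ribosome biogenesis in the adult against L4 difference, and from 2 to 1 for small RNA at L3, and the report gives the calls lost with an estimated correlation. Culture or reference wording as a block moved no count by over 1.5 times. Leaving out the major sperm proteins was planned and could not be run, since no such probe is named. Spot signal over background was not given in the sources used here, so its limit on low values could not be assessed. With a minimum of 2-fold, which by its construction takes fewer probes, counts were 2716 in adults, 1161 at L4, 234 at L3, 484 for glp-4 adult against L4 and 2223 for fem-3 against fem-1; 514 germline probes were higher in fem-1 and 433 in neither class. With quantile normalization the counts were 222 at L2 (164 higher, 58 lower), 9 for the L3 against L2 difference and 573 for glp-4 adult against L4 (265 higher, 308 lower); the cause was not tested. Centring moved the division for glp-4 adult against L4 from 282 higher and 629 lower to 410 and 433, and that for fem-3 against fem-1 from 2555 and 2058 to 1913 and 2445. With a value on every array 10 probes passed at L2, where fewer probes are tested. Fits of the compared arrays alone, with fewer samples behind the spread, gave 29 at L3, 0 at L2, 253 for the adult against L4 difference, 186 for the L4 against L3 difference, 488 for glp-4 adult against L4 and 20 for glp-4 L4 against L3. With batch numbers as a block the counts were 25 at L2, 1 for the L3 against L2 difference, 451 for glp-4 adult against L4 and 27 for glp-4 L4 against L3, and the division at L3 was 179 higher and 168 lower; the cause was not tested. Within the 2 reference wordings, with fewer arrays each, 1052 and 742 passed at L4 and 46 and 16 at L3. With germline defined at L4 alone, which takes fewer probes, 487 were higher in fem-1 and 263 in neither class.

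Leaving out 1 array at a time gave ranges of 3512 to 4520 in adults, 1571 to 2292 at L4, 148 to 449 at L3, 10 to 299 at L2, 260 to 1121 for the adult against L4 difference and 201 to 485 for L4 against L3. The ranges were 0 to 33 for L3 against L2, 548 to 940 for glp-4 adult against L4, 20 to 43 for glp-4 L4 against L3, 2903 to 5002 for fem-3 against fem-1, 575 to 625 for germline probes higher in fem-3, 921 to 1257 for those higher in fem-1 and 623 to 1041 for those in neither; the cause of these moves was not tested. The report names the arrays that moved a total by over 1.5 times. Totals held but lower probes at L4 fell from 906 to 587 or 591 without wild-type replicate 1 or 2, and at L3 from 120 to 79 without wild-type replicate 4. Higher probes fell at L3 from 239 to 157 without glp-4 replicate 4, in glp-4 adult against L4 from 282 to 186 without adult replicate 1, and for the adult against L4 difference from 539 to 346 without wild-type L4 replicate 4. Lower probes of that difference fell from 188 to 124 without glp-4 adult replicate 2 and to 96 with quantile normalization, and those of L4 against L3 ranged from 5 to 101 around 18, with 384 higher and 101 lower without wild-type L4 replicate 4. Where this left a group with 2 arrays, its spread was pooled with the other groups. For 274 combinations of a named gene and a comparison, of 4288 values under the alternatives 3728 kept direction and side of the threshold, 511 lost the call, 43 gained it and 6 reversed, each of a gene not called in that comparison. Of 214 combinations that were called, 101 lost the call under at least 1 alternative and 113 under none. cpg-22 at L4 turned from -0.30 to 0.55 within the reference wording of the higher lot numbers and to 0.0198 without wild-type L4 replicate 4, the highest of a leave-one-out range that starts at -0.63. cpg-20 in glp-4 L4 against L3 ranged from -0.0446 to 0.26, with negative values without glp-4 L4 replicate 2 or 4 or glp-4 L3 replicate 4. cpg-22 in fem-3 against fem-1 ranged from -0.20 to 0.0155, positive without fem replicate 4; the cause was not tested.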

Other observations

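The symbol families and the neighbour counts in this part were not planned at the outset; the families were chosen after the data were seen, and the neighbour test before its result was seen.

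Gene families that share a symbol were also tested as groups, and no family call given here held with an estimated correlation where that could be computed. Of 6 msrp genes, 5 were higher in fem-3 worms (median 3.41, family adjusted p = 7.57e-04, and adjusted p = 0.481 with an estimated correlation), msrp-2 by 4.93 ± 0.25, msrp-4 by 3.99 ± 0.31 and msrp-3 by 3.60 ± 0.19, while msrp-7 stood at 0.19 ± 0.19. At L4 4 of 5 msrp genes were higher in wild type than in glp-4 (median 1.79, family adjusted p = 5.35e-05), and 4 of 5 gained from L3 to L4 (median 1.58, family adjusted p = 1.93e-07). The gldi genes went the other way between the fem mutants, with 5 of 7 higher in fem-1 (median -1.02, family adjusted p = 0.0134, and adjusted p = 0.524 with an estimated correlation), although gldi-10 was higher in fem-3 by 2.88 ± 0.43.

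In wild-type adults, 8 of 16 srlf genes were lower than in glp-4 and srlf-13 was higher by 1.20 ± 0.20 (median -1.07, family adjusted p = 0.0364, and adjusted p = 0.173 with an estimated correlation). All 5 spig genes (median -1.50), 5 of 6 dbd genes (median -1.33), 3 of 3 kola genes (median -1.63) and 4 of 5 ctsa genes (median -0.90) were lower as single genes, but the family tests gave adjusted p = 0.0512, 0.0704, 0.0583 and 0.0626. Translation initiation factor genes (eif) rose in 5 of 6 cases (median 1.01, family adjusted p = 0.0248, and adjusted p = 0.329 with an estimated correlation), and RNA-binding motif genes (rbm), some of which also stand in the splicing list, in 4 of 6 (median 0.96, family adjusted p = 0.0196, and adjusted p = 0.329 with an estimated correlation).

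It was asked as a hypothesis whether germline genes of 1 class lie next to each other among the tested genes of a chromosome. Germline genes higher in fem-3 formed 103 neighbouring pairs, against a mean of 52.8 in 10000 shuffles within chromosomes (ratio 1.95, permutation p = 0.0001, the smallest these shuffles can give). Those higher in fem-1 formed 90 pairs against 54.8 (ratio 1.64, permutation p = 0.0001), those in neither class 35 against 19.6 (p = 0.0008), and genes lower in wild type 281 against 227 (ratio 1.24, p = 0.0001). Shared expression of neighbours, operons, tandem gene copies and cross-hybridization between such copies may each contribute, and they were not separated.

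Of the arrays compared with a reference, 5 correlated better with another group than with their own: glp-4 L2 replicate 1 with wild-type L2 (0.766 against 0.651), wild-type L3 replicates 4 and 1 with wild-type L2 (0.734 against 0.714 and 0.715 against 0.688), and glp-4 L3 replicates 2 and 1 with glp-4 L4 (0.755 against 0.753 and 0.706 against 0.702).

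The oocyte set of wild-type L3 replicate 2 stood at -0.53, with -0.60 as the highest of the other L3 arrays, and its mean correlation across probes with the adult arrays was 0.268, against at most 0.209 for the other L3 arrays.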
